A study of Mus musculus with 8 samples.

How the data were processed

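RNA from AML12 cells, a mouse hepatocyte line, was measured on Affymetrix MoGene 2.0 ST arrays in 2 groups of 4 samples. One group stably expressed Zfp125, which encodes a zinc finger protein, and the other carried the empty vector. Both were selected with G418 and kept in control medium, and column-purified total RNA was amplified and labelled as cDNA, per the labels' protocols. Replicate numbers 1 to 4 in each group come from the sample titles. The labels do not say whether the 4 samples of a group are separate cultures, transductions or selected lines, so the p-values measure only the spread between these samples, which may be technical.

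The deposited values are log2 expression values, 1 for each of 41345 transcript clusters on each array. That they are on the log2 scale was read from the values, which had medians of 4.32 to 4.37 on the 8 arrays. Affymetrix Expression Console and Transcriptome Analysis Console were used, per the submitters' processing notes. Their versions, the background correction and the normalization between arrays are not given in the sources used here. No array was normalized again in the principal analysis, and no detection call or background level was used. Pearson correlations between any 2 arrays over all clusters were 0.977 to 0.984, and no 2 arrays held identical values. The number of arrays limits the precision: the median SD within a group over the tested genes was 0.15 in empty vector cells and 0.132 in Zfp125 cells on the log2 scale.

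Clusters were named through the platform annotation, in which 23521 clusters carried 1 gene symbol, 1814 carried several and 16010 were unnamed here. Symbols were updated through the Entrez identifier to the GRCm38.p6 RefSeq gene table, which held the identifier of 23328 clusters. The annotation symbol was kept for the other 193. Only clusters with 1 symbol were tested for named genes. Of 1082 genes with more than 1 cluster, the cluster with the highest mean over all 8 arrays was used, which left 22180 genes. Zfp125 had no cluster of its own in these tables and is not analysed here, so the labels were not checked against the expressed gene.

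Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over the 22180 genes. A gene was called changed at an adjusted p under 0.05. Changes are Zfp125 minus empty vector cells on the log2 scale, with the standard error of limma's moderated test. All adjusted p-values of genes come from this test unless said otherwise, and all tests were two-sided. Lists of genes were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over 24 lists. Camera with the correlation estimated for each list, camera on ranks and fry, which asks whether the genes of a list move on balance one way, were alternatives. The lists covered hepatocyte lipid metabolism, liver functions, stress responses, proliferation and markers of other cell types. Of their 871 genes, 796 were measured and 75 are not analysed here, 33 of them because their cluster carried several symbols. Counts of changed members are given over all genes and adjusted over the list alone. Exact permutation tests over the 70 assignments of 4 of 8 arrays cannot give a p below 0.0286.

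The tests, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule names Zfp125 and Foxo1, the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, and the 2 to 3 measured members of each list with the smallest p. It also names every changed member of the list of lipoprotein assembly, apolipoproteins and lipid efflux. Predicted genes with Riken or Gm names may be counted without discussion. Genes outside the rule were chosen after their values were seen. These are Insig1, Plg, Gpt, Slc2a2, Cyp2j6, Cyp4v3, Cyp2d26, Bnip3, Il1rn, Il1r1, Mt2, Alb, Serpina1c, Rbp4, Apob, Ttr, Hnf4a, Zim1, Sgce, Peg3, Sema3c, Efnb2, Ntn4, Lamc1, Lama5, Agrn, Itga5, Dusp1, Rgs2, Tsc22d3, Fkbp5, Per1 and the snoRNA host genes. Lists of glucocorticoid targets and imprinted genes, and all tests of small RNA classes, were likewise added afterwards.

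The gene test was run on simulated data with 200 of 22180 genes changed in the Zfp125 against empty vector comparison. It recovered 47.1% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 98.5% of those changed by 2, with 6 false calls among 168. A simulated list lowered by 0.2 was recovered, and 0 of 23 unshifted lists were called; the simulated genes were independent of each other, so this does not test the preset correlation. Alternatives covered normalization between arrays, a filter on dim clusters, variance moderation, array weights, the choice among clusters of a gene, all clusters of the table, the replicate number as a block and leaving out each array. Plots were drawn with matplotlib 3.10.9.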

Results

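Gene expression was measured in AML12 cells that stably express Zfp125 and in AML12 cells with the empty vector, with 4 arrays in each group. AML12 is a hepatocyte line from mouse liver that makes albumin and other secreted liver proteins in culture. The series asks which genes differ in expression when Zfp125 is expressed. All values are on the log2 scale, errors of changes are standard errors, errors of means are SDs, and n = 4 arrays in each group.

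In Zfp125 cells, 9 of 41 genes of the lipoprotein list, 8 of 38 of hepatocyte identity, 4 of 33 of coagulation and complement and 5 of 26 of the acute phase fell, and 0, 1, 0 and 1 rose. Each list lay lower by camera and passed with fry (fry adjusted p = 0.00641, 0.00251, 0.0123 and 0.0044). With an estimated correlation in camera none passed (adjusted p = 0.0814, 0.0814, 0.0944 and 0.0814). The mRNA of the acute phase apolipoprotein Saa3 fell by 1.74 ± 0.12 on the log2 scale, a 3.35-fold lower level (adjusted p = 1.34e-05). Haptoglobin, the hemoglobin-binding plasma protein encoded by Hp, fell by 1.66 ± 0.13 (adjusted p = 3.75e-05). Apoc1, an apolipoprotein of triglyceride-rich particles, fell by 1.39 ± 0.11 (adjusted p = 4.78e-05). Among the genes that rose was Foxa1, a liver transcription factor, which was 0.86 ± 0.11 higher (adjusted p = 0.00179).

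Of 22180 genes, 240 changed, 99 of them higher and 141 lower in Zfp125 cells. Changes of at least 2-fold were lower for 26 genes and higher for 1, the small nucleolar RNA Snord19. At an unadjusted p under 0.05 there were 2424 genes, and the median change over all genes was -0.00268. The count depends on the test: 26 genes were called without variance moderation and 498 with a trended, robust prior. It ranged from 109 to 187 when 1 array was left out, lowest without replicate 1 of the Zfp125 cells.

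**Figure D1:**
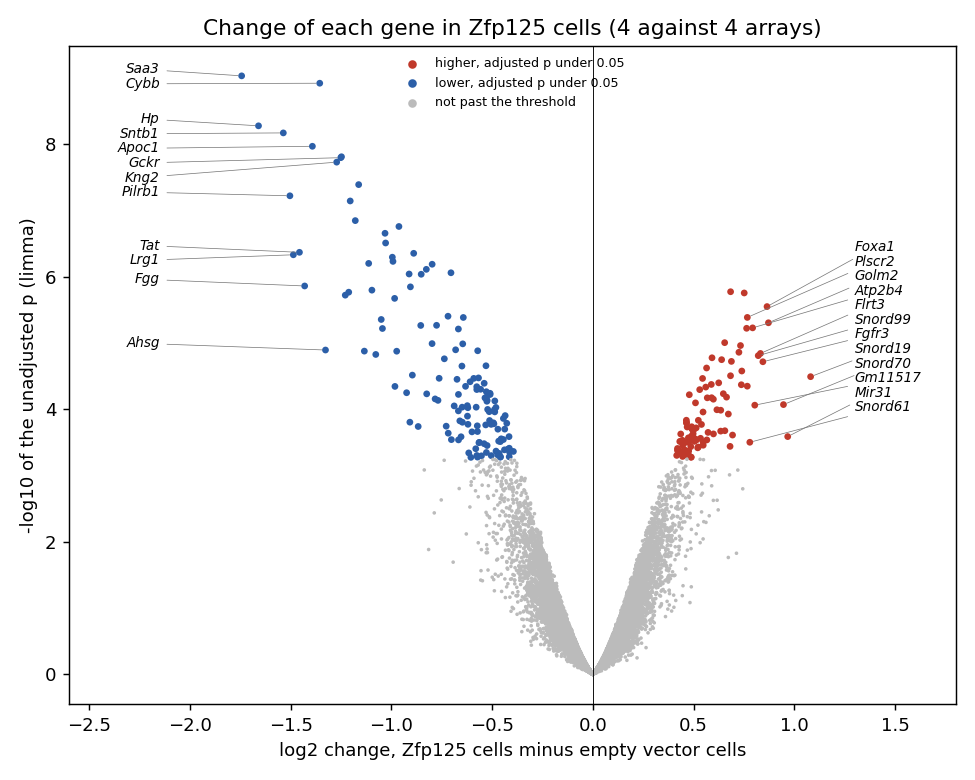
Each point is a gene, with its log2 change in Zfp125 minus empty vector cells on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; 99 genes in red were higher and 141 in blue were lower at an adjusted p under 0.05. The 12 largest falls, led by Saa3 at -1.74, reach further from 0 than the 12 largest rises, led by Snord19 at 1.08.

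The largest falls included several further plasma proteins. Fgg, the gamma chain of fibrinogen, fell by 1.43 ± 0.17 from a mean of 7.79 ± 0.22 to 6.36 ± 0.41. Ahsg, which encodes fetuin A, fell by 1.33 ± 0.20, Kng2, a kininogen, by 1.27 ± 0.11, and Lrg1, a secreted glycoprotein induced in inflammation, by 1.49 ± 0.16. Tat, the tyrosine aminotransferase that glucocorticoids induce in liver, fell by 1.46 ± 0.16. Gckr, the regulatory protein of glucokinase, fell by 1.25 ± 0.10. Cybb, the catalytic subunit of the NADPH oxidase of phagocytes, fell by 1.36 ± 0.09 from 8.30 ± 0.11 to 6.94 ± 0.09. Sntb1, a syntrophin of the dystrophin complex, fell by 1.54 ± 0.12, and Pilrb1, an immune receptor, was 2.84-fold lower. The adjusted p-values of these 9 genes from limma lay between 1.34e-05 and 0.00537, and each call held when any 1 array was left out. Without variance moderation 5 of these calls ended, those of Pilrb1 (adjusted p = 0.0564), Tat (0.0881), Lrg1 (0.0926), Fgg (0.106) and Ahsg (0.164).

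The largest rises were small RNA genes and genes for membrane proteins and a transcription factor. Snord19 was 1.08 ± 0.18 higher (adjusted p = 0.0101), Snord70 0.95 ± 0.17 (adjusted p = 0.017), Snord99 0.82 ± 0.12 (adjusted p = 0.00584) and Snord61 0.78 ± 0.16 (adjusted p = 0.0361). The microRNA gene Mir31 was 0.97 ± 0.20 higher (adjusted p = 0.0339). Snord19 and Mir31 were dim in empty vector cells, with means of 3.85 ± 0.42 and 3.99 ± 0.51, below the median of all clusters, 4.34. Among protein-coding genes, Golm2 rose by 0.87 ± 0.12, the growth factor receptor Fgfr3 by 0.84 ± 0.13, the adhesion protein Flrt3 by 0.83 ± 0.13, the plasma membrane calcium pump Atp2b4 by 0.79 ± 0.11 and Plscr2, a phospholipid scramblase family member, by 0.77 ± 0.10. The calls of Mir31, Snord61 and Snord70 ended on leaving out 1 array in 7, 6 and 3 of 8 cases, with adjusted p-values up to 0.116, 0.131 and 0.059.

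Foxo1, a transcription factor of the insulin and fasting response, had means of 6.70 ± 0.08 in empty vector cells and 6.42 ± 0.14 in Zfp125 cells, a change of -0.27 ± 0.10 that did not pass the test (adjusted p = 0.274). Its second cluster had a change of -0.11.

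In the list of lipoprotein assembly, apolipoproteins and lipid efflux, 9 of 41 measured genes fell and 0 rose. Besides Apoc1, these were Apoh with -1.04 ± 0.15, Apof with -0.99 ± 0.11, Apoc2 with -0.91 ± 0.11, Lcat with -0.74 ± 0.11, Apon with -0.68 ± 0.10, Apoa1 with -0.61 ± 0.13, Apoc3 with -0.57 ± 0.09 and Apoe with -0.51 ± 0.09. Apoa1 is the main protein of high-density lipoprotein, Lcat the plasma enzyme that esterifies its cholesterol, and Apoc2 the cofactor of lipoprotein lipase. Apob, the core protein of very-low-density lipoprotein, had a change of -0.07 ± 0.09 (adjusted p = 0.844). Adjusted over the list alone, 12 fell and 1 rose. The list lay lower than other genes (camera, adjusted p = 1.7e-07; adjusted p = 0.0814 with an estimated correlation), with a median change of -0.08. The call of Apoa1 ended in 7 of the 8 omissions of 1 array (adjusted p up to 0.163). It also ended with quantile normalization again (adjusted p = 0.0507) and with means of clusters (adjusted p = 0.0517). Apoa1 has only 1 cluster, so in the latter setting its change was the same and only its adjusted p moved. The call of Apoe ended without replicate 1 of the Zfp125 cells (adjusted p = 0.0531). Without moderation, the calls of Apoe (adjusted p = 0.0564), Apof (0.0579), Apoc2 (0.0711), Apon (0.0819), Lcat (0.109), Apoh (0.121) and Apoa1 (0.26) ended. Those of Apoc1 and Apoc3 held.

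**Figure D2:**
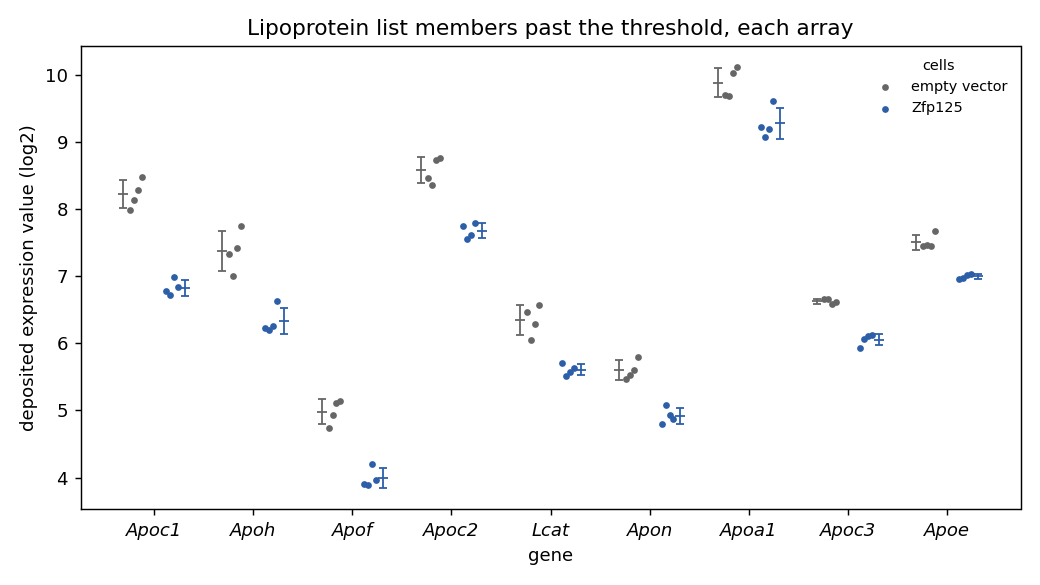
Deposited log2 expression values of the 9 lipoprotein genes that fell, with a point for each array, empty vector cells in grey and Zfp125 cells in blue, and the mean with an SD bar at the side. For each of the 9 genes all 4 Zfp125 values lie below all 4 empty vector values.

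In the list of cholesterol synthesis and uptake, 4 of 20 measured genes fell and 0 rose (7 fell adjusted over the list alone), with a median change of -0.21. Of the enzymes of the pathway, Nsdhl fell by 0.63 ± 0.11 and Fdps fell by 0.61 ± 0.10. In addition, Insig1, an endoplasmic reticulum regulator of sterol sensing, fell by 0.60 ± 0.12 and the sterol carrier Stard4 fell by 0.50 ± 0.10. The list lay lower than other genes (camera, adjusted p = 9.99e-09; adjusted p = 0.0944 with an estimated correlation). The calls of Stard4 and Insig1 ended in 6 and 5 of the 8 omissions, with adjusted p-values up to 0.0993 and 0.103.

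In the list of lipid binding and fatty acid uptake, 1 of 33 measured genes fell and 0 rose with the brightest cluster of each gene, and 8 fell and 1 rose adjusted over the list alone. The gene that fell was Fabp1, the liver fatty acid binding protein, by 0.98 ± 0.17 (adjusted p = 0.0119). Fabp5 had a change of -0.48 ± 0.11 (adjusted p = 0.0522) in its brightest cluster and of -1.25, -1.08 and -1.19 in its other 3. With the mean of its clusters it passed the test (adjusted p = 6.20e-04), so its call rests on the choice of cluster. The fatty acid carrier Cd36 had a change of -0.60 ± 0.15 (adjusted p = 0.0813). That list was lower by camera (adjusted p = 0.00179; adjusted p = 0.118 with an estimated correlation). In the list of fatty acid and triglyceride synthesis, 2 of 33 fell, 0 rose, and 7 fell and 1 rose adjusted over the list alone. They were the stearoyl-CoA desaturase Scd1 with -0.97 ± 0.15 and Mlxipl, the carbohydrate response factor, with -0.59 ± 0.10; Slc25a1 had a change of -0.38 ± 0.09 (adjusted p = 0.0682). The list was lower by camera (adjusted p = 0.0161; adjusted p = 0.21 with an estimated correlation), which ended without replicate 1 of the empty vector cells (adjusted p = 0.0553) and on ranks (adjusted p = 0.146).

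Lists of bile acid synthesis and transport, fatty acid oxidation, oxidative phosphorylation and thyroid hormone targets did not pass the test. Of 31 bile acid genes 2 fell, the export pump Abcc2 by 0.62 ± 0.11 and the peroxisomal oxidase Acox2 by 0.65 ± 0.13, 0 rose, and Fgfr4 had a change of 0.37 ± 0.10 (camera, adjusted p = 0.178); 2 fell and 1 rose adjusted over the list alone. Leaving out 1 array ended the call of Acox2 in 6 cases (adjusted p up to 0.105) and that of Abcc2 in 5 (adjusted p up to 0.065). Of 37 oxidation genes 0 changed and 2 fell adjusted over the list alone, with Acaa2 at -0.41 ± 0.10, Bdh1 at -0.45 ± 0.12 and Acot3 at -0.32 ± 0.10 (camera, adjusted p = 0.18). Of 46 oxidative phosphorylation genes 0 changed, also adjusted over the list alone, with Ndufa2, Sdhc and Cox7b each at -0.26 (camera, adjusted p = 0.106). The second cluster of Cox7b had a change of -0.05. Of 19 thyroid list genes only Scd1 changed over all genes, 1 fell and 1 rose adjusted over the list alone, Me1 was at 0.42 ± 0.11 and Bcl3 at -0.28 ± 0.09 (camera, adjusted p = 0.544). The oxidative phosphorylation list passed as lower without empty vector replicate 3 (adjusted p = 0.0122) or Zfp125 replicate 2 (adjusted p = 0.0339), fatty acid oxidation without Zfp125 replicate 2 (adjusted p = 0.0313), and bile acids among clusters above the median level (adjusted p = 0.0251).

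Among hepatocyte identity genes, 8 of 38 measured fell and 1 rose, and 15 fell and 3 rose adjusted over the list alone. The 3 fibrinogen chains fell together, Fga by 1.11 ± 0.13 and Fgb by 1.21 ± 0.15 beside Fgg, and Ahsg, Apoh, Serpina1c (-0.67), Rbp4 (-0.49) and Alb made up the rest. Alb, the gene of serum albumin, fell by 0.48 ± 0.09 from 12.96 to 12.48, while transthyretin, Ttr, had a change of 0.08 ± 0.10 (adjusted p = 0.836). The 1 that rose was Foxa1, and the hepatocyte factor Hnf4a had a change of -0.38 ± 0.09 (adjusted p = 0.0562). The list lay lower than other genes (camera, adjusted p = 1.66e-09; adjusted p = 0.0814 with an estimated correlation). The calls of Rbp4, Serpina1c and Alb ended in 6, 5 and 4 of the 8 omissions of 1 array, with adjusted p-values up to 0.0941, 0.0707 and 0.0716.

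In the list of coagulation and complement factors, 4 of 33 fell and 0 rose, and 10 fell adjusted over the list alone. These were Serping1, the C1 inhibitor, by 0.85 ± 0.12, Serpinf2, the plasmin inhibitor, by 0.65 ± 0.10, plasminogen, Plg, by 0.58 ± 0.10 and prothrombin, F2, by 0.57 ± 0.09 (camera, adjusted p = 1.14e-08; adjusted p = 0.0944 with an estimated correlation). Of 26 acute phase genes, 5 fell and 1 rose, and 12 fell and 4 rose adjusted over the list alone. Beside Saa3 and Hp, hepcidin, Hamp, fell by 0.92 ± 0.16, the interleukin-1 receptor antagonist Il1rn by 0.91 ± 0.17 and the metallothionein Mt2 by 0.44 ± 0.09, while the receptor Il1r1 rose by 0.63 ± 0.12. Hamp was dim, with means of 3.97 in empty vector and 3.04 in Zfp125 cells, below the median of all clusters, 4.34. This list had the lowest median of the 24, -0.31 (camera, adjusted p = 2.31e-08; adjusted p = 0.0814 with an estimated correlation). The calls of Mt2, Il1rn and Il1r1 ended in 8, 6 and 4 of the 8 omissions of 1 array, with adjusted p-values up to 0.102, 0.0851 and 0.0791.

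Glucose metabolism was represented by a glycolytic and a gluconeogenic list. Of 30 glycolysis and hypoxia genes, 4 fell and 0 rose, and 10 fell adjusted over the list alone. The glycolytic enzymes Pgk1 and Ldha fell by 0.64 ± 0.09 and 0.51 ± 0.09, and the hypoxia-induced Egln3 and Bnip3 by 0.69 ± 0.12 and 0.70 ± 0.14 (camera, adjusted p = 4.04e-06; adjusted p = 0.0814 with an estimated correlation). Of 26 genes of gluconeogenesis and Foxo1 targets, 4 fell and 1 rose, and 7 fell and 4 rose adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0705). Besides Tat, the insulin-repressed Igfbp1 fell by 1.18 ± 0.12, alanine aminotransferase, Gpt, fell by 0.67 ± 0.11 and pyruvate carboxylase, Pcx, by 0.65 ± 0.09, and the glucose transporter Slc2a2 rose by 0.45 ± 0.10. The gluconeogenic list passed as lower among clusters above the median level (adjusted p = 0.0278) and without empty vector replicate 2 (adjusted p = 0.0185) or Zfp125 replicate 2 (adjusted p = 0.0332). The calls of Bnip3, Slc2a2 and Egln3 ended in 7, 7 and 2 of the 8 omissions of 1 array, with adjusted p-values up to 0.116, 0.147 and 0.0602.

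Of 45 measured cytochrome P450 and conjugation genes, 4 fell and 2 rose, and 6 fell and 3 rose adjusted over the list alone. The sulfotransferase Sult1a1 fell by 1.03 ± 0.11, the epoxide hydrolase Ephx2 by 0.85 ± 0.10, Cyp4v3 by 0.66 ± 0.13 and Cyp2d26 by 0.58 ± 0.13, while Cyp2j5 and Cyp2j6 rose by 0.56 ± 0.09 and 0.52 ± 0.10 (camera, adjusted p = 0.0539). The list passed as lower with median centring (adjusted p = 0.0454), a trended, robust prior (0.0433), array weights (0.0403), means of clusters (0.0484), the replicate block (0.0274), and without replicate 2 of the empty vector cells (0.0189) or of the Zfp125 cells (0.0221). Of 32 NRF2 targets and glutathione genes, 2 fell and 0 rose, the glutathione transferases Gstp1 by 0.65 ± 0.12 and Gsta4 by 0.51 ± 0.09, and 4 fell adjusted over the list alone. The carbonyl reductase Cbr1 had a change of -0.56 ± 0.13 (adjusted p = 0.0549) and of -0.21 in its second cluster. The list was lower by camera (adjusted p = 0.0293; adjusted p = 0.284 with an estimated correlation), which ended with fry (0.061), on ranks (0.0947), and without empty vector replicates 1 (0.163) or 4 (0.0758) or Zfp125 replicate 3 (0.0687). Leaving out 1 array ended the calls of Cyp2d26, Cyp4v3, Cyp2j6, Gstp1, Cyp2j5 and Gsta4 in 7, 6, 5, 3, 1 and 1 of 8 cases, with adjusted p-values up to 0.155, 0.0898, 0.0925, 0.0615, 0.0506 and 0.0524.

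Stress response genes were lower in part. Of 33 genes of the unfolded protein and integrated stress response, 3 fell and 0 rose (6 fell adjusted over the list alone), the chaperone cofactor Sdf2l1 by 0.70 ± 0.08, Creld2 by 0.44 ± 0.08 and Atf5 by 0.44 ± 0.09 (camera, adjusted p = 0.001; adjusted p = 0.25 with an estimated correlation). Of 24 p53 targets, 1 fell, the cell cycle inhibitor Cdkn1a with -0.67 ± 0.09, 0 rose, and 2 fell adjusted over the list alone; Btg2 had a change of -0.45 ± 0.11 and Pmaip1 of -0.50 ± 0.16 (camera, adjusted p = 9.43e-04; adjusted p = 0.143 with an estimated correlation). The calls of Atf5 and Creld2 ended in 8 and 7 of the 8 omissions of 1 array, with adjusted p-values up to 0.137 and 0.0821.

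Of 56 cell cycle genes, 1 changed: cyclin D1, Ccnd1, fell by 0.65 ± 0.12. Kif23 and Ccnb2 had changes of 0.59 ± 0.14 (adjusted p = 0.066) and 0.37 ± 0.09 (adjusted p = 0.0782), and 2 rose and 1 fell adjusted over the list alone. The list was higher by camera, with a median of 0.04 (adjusted p = 0.0415; adjusted p = 0.589 with an estimated correlation). This ended with quantile normalization again (adjusted p = 0.0692), among clusters above the median (0.14) or 25th percentile level (0.0671), with fry (0.496), and without empty vector replicates 2 or 4 (0.0952 and 0.283) or Zfp125 replicates 3 or 4 (0.207 and 0.56). The call of Ccnd1 ended in 6 of the 8 omissions of 1 array (adjusted p up to 0.0959).

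Of 50 interferon response genes, the antiviral membrane protein Ifitm3 fell by 1.20 ± 0.11 (adjusted p = 1.45e-04) and 0 rose. Mx2 and Stat2 had changes of -0.45 ± 0.11 and -0.31 ± 0.11, and 2 fell adjusted over the list alone (camera, adjusted p = 0.115). The list passed as lower among clusters above the median (adjusted p = 0.0251) or 25th percentile level (adjusted p = 0.0463). Of 30 NF-kB and chemokine genes 0 changed in limma, against 1 that fell adjusted over the list alone. Cxcl1, Cxcl16 and Icam1 had changes of -0.51 ± 0.12, -0.42 ± 0.14 and -0.27 ± 0.08, and the list was lower by camera (adjusted p = 0.0293; adjusted p = 0.239 with an estimated correlation), which ended with fry (0.0753) and without empty vector replicate 1 (0.125) or Zfp125 replicates 1 or 3 (0.0654 and 0.0687).

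Of 24 fetal liver, biliary and progenitor markers, 2 rose and 0 fell, the cilium protein gene Pkhd1 by 0.48 ± 0.10 and the transcription factor Onecut2 by 0.45 ± 0.10, and 4 rose and 1 fell adjusted over the list alone. Jag1 had a change of 0.33 ± 0.09, and the list was higher by camera (adjusted p = 0.0293; adjusted p = 0.118 with an estimated correlation), which ended on ranks (0.0984) and without empty vector replicate 4 (0.0667). The calls of Onecut2 and Pkhd1 ended in 7 and 6 of the 8 omissions of 1 array, with adjusted p-values up to 0.149 and 0.124.

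The lists of stellate, macrophage and endothelial markers showed no shift past the test. The macrophage list was dim, with mean levels of 3.93 in empty vector and 3.94 in Zfp125 cells, below the median of all clusters, 4.34. The endothelial list lay close to that median, at 4.38 and 4.34. A shift of these dim markers could therefore be missed. Of 49 stellate cell, fibroblast and matrix genes, the matricellular protein Ccn2 rose by 0.46 ± 0.10 (adjusted p = 0.0475), 0 fell, and 2 fell and 1 rose adjusted over the list alone. Its second cluster had a change of 0.16, and leaving out any 1 of the 8 arrays ended the call (adjusted p of 0.0567 to 0.135). Fn1 and Col8a1 had changes of -0.34 ± 0.08 and -0.43 ± 0.11, and the list had a median of -0.02 and a mean of -0.0017 although camera placed it higher (adjusted p = 0.949). Of 29 macrophage and leukocyte genes 0 changed, also adjusted over the list alone, with Laptm5 at -0.20, Nkg7 at 0.21 and Cx3cr1 at 0.19 and a median of -0.01, against a mean of 0.0116 and a camera direction that was higher (adjusted p = 0.57). Of 25 endothelial genes 0 changed, also adjusted over the list alone, with Eng at -0.20, Tek at 0.17 and Gpihbp1 at -0.15 (camera, adjusted p = 0.292).

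Across the 24 lists, 12 were lower and 2 higher with the preset correlation, and none passed with the correlation estimated for each list, where the smallest adjusted p was 0.0814. With fry, 11 passed.

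**Figure D3:**
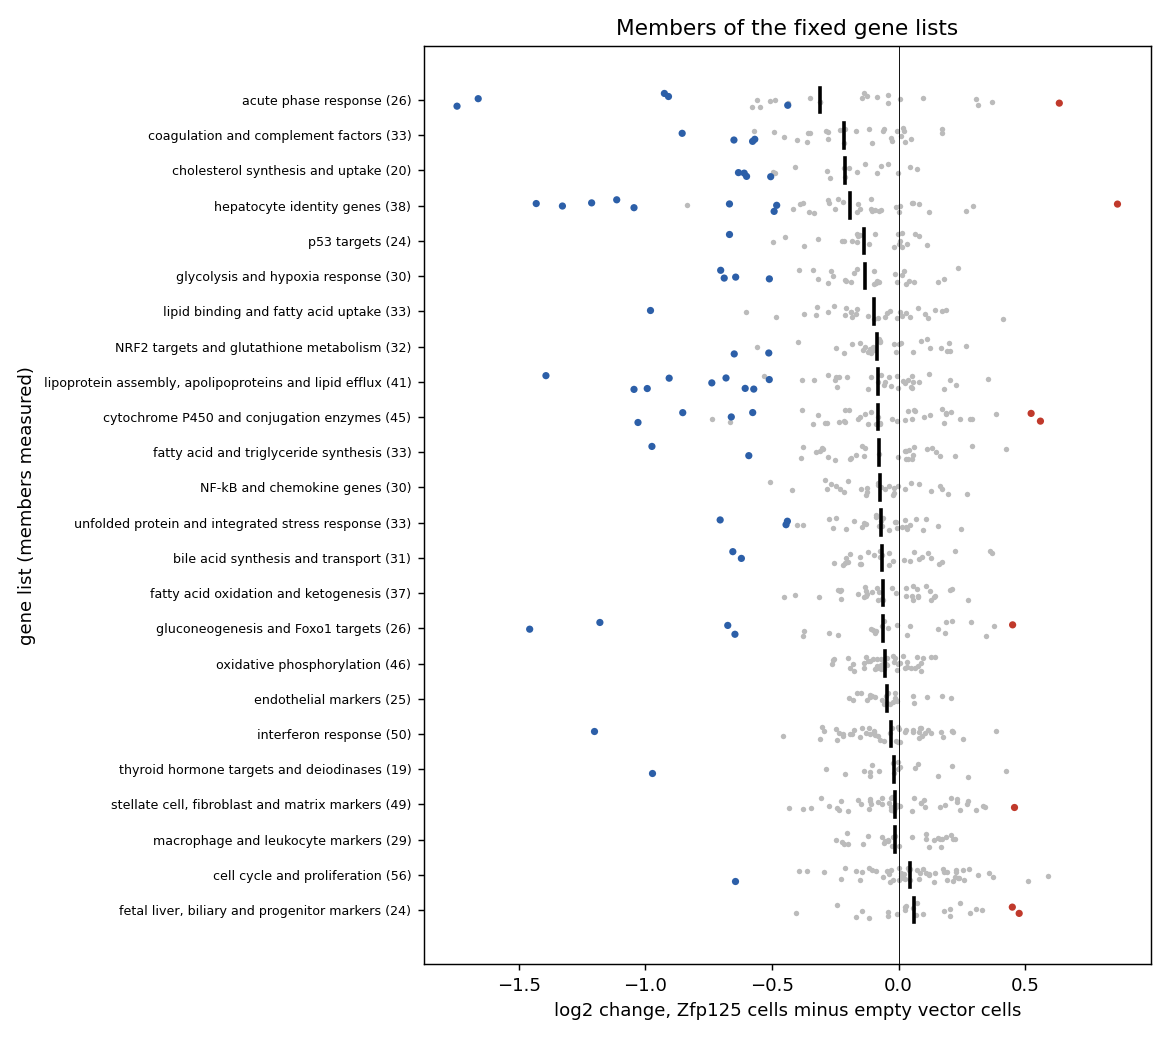
Log2 change of every measured member of the 24 lists, Zfp125 minus empty vector cells, with members that rose in red, members that fell in blue, others in grey and the median of each list as a black bar. The acute phase list has the lowest median, -0.31, and the fetal liver, biliary and progenitor list the highest, 0.06.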

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

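The rule for samples that stand apart was set in advance, and how to fit the clusters outside the tested genes was settled after a first result was seen. In 14 of 258 groups of 4 arrays, over the named genes, 1 array lay far from the other 3 (a gap over range above Dixon's 95% critical value). Chance alone gives about 12.9 such groups.

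In empty vector cells, the array that stood apart was replicate 3 for Golm2 (4.92, the others 5.19 to 5.22), replicate 1 for Btg2 (6.90) and replicate 2 for Slc2a2 (9.79). It was replicate 4 for Acaa2 (8.56) and for Apoe (7.67, the others 7.45 to 7.46).

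In Zfp125 cells it was replicate 1 for Pilrb1 (6.43) and Slc25a1 (7.58), replicate 2 for Stard4 (5.76) and Onecut2 (8.21), and replicate 3 for Cox7b (6.16). It was replicate 4 for Gstp1 (9.85), Laptm5 (3.77), Apoh (6.63, the others 6.20 to 6.26) and Peg3 (11.21).

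Outside the tested genes, the 1814 clusters with several symbols held 7 that were higher and 11 that were lower in Zfp125 cells when fitted alone with limma, and 199 at an unadjusted p under 0.05. The 16010 unnamed clusters held 0 changed, with 1245 at an unadjusted p under 0.05. With both kinds in 1 limma fit, which was tried first, 0 of either kind changed, and 124 and 1305 had an unadjusted p under 0.05.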

How the results depend on the processing

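The count of 240 changed genes (99 higher, 141 lower) rose to 405 (182 and 223) among clusters above the median level and to 498 (228 and 270) with a trended, robust prior, which kept all 240. It fell to 26 (5 and 21; 23 shared) without moderation and to 61 (10 and 51) over all clusters of the table. Of at least 2-fold changes, 1 higher and 26 lower became 0 and 9 without moderation and 0 higher over all clusters. The causes were not tested, except that a filter lowers the number of genes tested. The other settings with all arrays, apart from the block, stayed within 1.5 times.

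With the replicate number as a block, 152 genes changed, 49 higher and 103 lower, 139 of them shared. Same-numbered arrays did not deviate together (correlations of -0.0526, -0.0528, 0.0365 and -0.0091), so the values showed no pairing by number. Whether same-numbered samples were handled together is not given in the labels.

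Leaving out 1 array gave 109 to 187 changed genes, 31 to 72 higher and 72 to 120 lower, 0 to 2 at least 2-fold higher and 23 to 33 at least 2-fold lower, with fewer samples in each fit. The changed genes numbered 109, 116 and 134 without Zfp125 replicates 1, 2 and 3, and 135 and 139 without empty vector replicates 3 and 4. Of 91 named genes that were called, 55 kept the call in all 8 omissions, as did 7 of the 9 lipoprotein genes, and 12 kept it under every alternative run. Without moderation 77 of the 91 calls ended, and with the replicate block 18. The other settings with all arrays ended the calls of Ccn2 and Apoa1 (quantile normalization again, means of clusters), of Ccn2, Atf5, Onecut2, Peg3, Lama5 and Slc2a2 (median centring), and of Slc2a2 and Cyp2d26 (array weights), with adjusted p-values of 0.0506 to 0.0655, and 0.217 for Ccn2 with means of clusters.

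Of the 24 lists, 12 were lower and 2 higher. With an estimated correlation 0 and 0 passed. The 2 higher became 1 with quantile normalization again, with either filter on dim clusters, with fry and with ranks. Omissions gave 9 to 16 lower and 0 to 2 higher. The stellate list, far from the threshold in every setting, turned to lower among clusters above the median level (adjusted p = 0.45) and above the 25th percentile (0.908), with fry (0.945), with ranks (0.91), and without empty vector replicate 2 (0.945) or Zfp125 replicates 1, 3 or 4 (0.917, 0.933 and 0.883; 0.661 to 0.945 over the omissions). The macrophage list turned to lower without empty vector replicate 1 (0.888; 0.169 to 0.888 over the omissions). Tsc22d3, at 0.02, became -0.0426 without empty vector replicate 3 and -0.0396 without Zfp125 replicate 1 (-0.0426 to 0.0719 over the omissions). The causes were not tested. The alternatives for Zfp125 itself were not run because it is not analysed here, and the lists were not run without moderation. No background level was used here, so what dim signal limits was tested only through the filters.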

Other observations

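These tests were chosen after the result was seen: those of a mixture of cells, the glucocorticoid test with an estimated correlation, the small RNA test on brighter microRNA genes, and that of all snoRNA hosts. Outside the lists, some genes were picked from the rises by their values, with no test of the groups they belong to. Sema3c rose by 0.75 ± 0.09, Efnb2 by 0.76 ± 0.11 and Ntn4 by 0.68 ± 0.08 (limma, adjusted p = 0.00122, 0.00297 and 0.00122). Agrn, Lamc1 and Lama5 rose by 0.48 ± 0.08, 0.44 ± 0.09 and 0.42 ± 0.09, and Itga5 by 0.47 ± 0.10. The calls of Lamc1, Lama5, Itga5 and Agrn ended in 8, 8, 7 and 1 of the 8 omissions of 1 array, with adjusted p-values up to 0.116, 0.145, 0.104 and 0.0545.

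The imprinted genes Sgce and Zim1 rose by 0.69 ± 0.11 and 0.68 ± 0.11. Zim1 was dim, with means of 3.55 in empty vector and 4.23 in Zfp125 cells, below the median of all clusters, 4.34. Among 38 other imprinted genes 1 rose, Peg3 by 0.45 ± 0.10, and 0 fell. The list had a median of 1.5e-04 and no shift past the test (camera p = 0.317, exact permutation p of its mean = 0.114). No rise of imprinted genes as a class was therefore seen. Dim members were not set apart, so a rise limited to expressed members was not tested. The call of Peg3 ended in 7 of the 8 omissions of 1 array (adjusted p up to 0.142).

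Over 137 genes of the lipoprotein, hepatocyte identity, coagulation and acute phase lists the median change was -0.17, which argues against a bias that depends on level, since 95% of random lists matched on level had medians between -0.03 and 0.03. A mixture with cells lacking liver genes, if it lowered these genes alike, is argued against as the whole cause. Of 32 bright identity genes, the 95% interval of 18 excludes their own median of -0.26 (1.6 by chance), 9 above it and 9 below. Whether a mixture would give equal falls on these arrays, and whether the other cells would lack every one of these genes, was not tested. A mixture with unequal falls therefore stays open. A smaller share of such cells stays open, with 17 of the 32 intervals below 0 and 3 above; that 25 exclude -0.85, the median of the called genes, decides nothing, since those were selected for their fall. Lower glucocorticoid input also stays open: as first set, its test was met over 23 targets, without genes already seen such as Dusp1 at -1.03 and Rgs2 (camera p = 2.29e-04; 18 below 0; exact permutation p of their mean = 0.0286; 2 of 35 splits gave a camera p as small), with Fkbp5 at -0.18 but Tsc22d3 at 0.02 and Per1 at 0.13, while the p with an estimated correlation, added afterwards, was 0.0746. An effect of Zfp125 and a difference between selected lines are both untested, since the labels do not say how many lines each group holds, and 8 of the 23 targets are in the fixed lists, among them Mt2, 1 of the 2 targets that fell.

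Of 85 small nucleolar RNA genes 17 rose and 1 fell, the median change was 0.27, and the array medians were 0.19 to 0.39 in the 4 Zfp125 samples against -0.06 to 0.08 in the 4 empty vector samples (exact permutation p = 0.0286, the smallest possible). The test of better recovery of small RNA was not met: the median was -0.0077 over 478 microRNA genes, against 0.133 needed. Since most of those were dim, the 136 above the median level were also tested, with a median of 0.0413 (95% interval 0.0106 to 0.0863). The 95% intervals of medians in this paragraph come from resampling genes, so they leave out the spread between arrays. Whether these probes read short precursors or longer transcripts is not known here, so better recovery of small RNA stays open. The 6 snRNA genes, with a median of 0.0698 (95% interval -0.247 to 0.337), decide nothing either. Higher mature host transcripts were not seen. The 53 hosts of 70 of these genes had a median of 0.0281 (95% interval -0.0082 to 0.0556), against 0.13 needed, and 0 rose. As that interval leaves out the spread between arrays, it does not exclude them. A bias with level is argued against by matched random lists, whose upper 95% bound was 0.0395. The 13 hosts of the genes that rose had a median of 0.0674 (95% interval -0.0126 to 0.158) against 0.294, a bound that selection makes large, with 9 above 0, up to Rbmx at 0.36, and 4 below 0, down to Rpl17 at -0.29. Processing or stability of these RNAs may differ between the groups, a hypothesis that was not tested here, and the class was noticed among the largest rises before it was tested.

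Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave as many as 240 changed genes, and the highest other gave 0; for changes of at least 2-fold it was 27 against 0. Chance is excluded for the genes only at 1 of 35, the smallest share this design can give, and every other split mixes the groups, which widens its spread. For the lists chance is not excluded by this count. With the preset correlation 2 of 35 splits, the real one included, gave at least the real 14 lists. The other gave 15, but it only exchanged replicate 2 of the empty vector cells with replicate 2 of the Zfp125 cells. It thus still held part of the real contrast, so the count cannot decide whether chance gives as many lists. Splits with 2 arrays of each group on each side gave 0 to 3 lists.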
